A study of Mus musculus with 22 samples.

How the data were processed

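Bulk RNA was isolated with the Qiagen RNeasy Plus Mini kit and libraries were made with the Revelo RNA-Seq High Sensitivity kit, per the labels' protocols. The submitters' processing notes name cutadapt, featureCounts, DESeq2 and the mm10 build; the aligner and all versions are not given in the sources used here. The authors deposited a table for each ventricle whose values, a signal that is never negative, are gene counts divided by DESeq2 size factors, per the labels. The LV and RV tables were normalized separately, so tests were made within a table or on differences within a mouse, in which a constant factor between the tables drops out. Each header line has 2 empty cells between the gene column and the 11 sample names, while each row has 11 values. The names were read in order with the empty cells skipped, and each name was matched to its sample through the labels.

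Ensembl genes numbered 49671 for the LV and 49670 for the RV, of which 49326 and 49325 had a symbol in the GENCODE annotation of mm10, the source of all coordinates. None of the 13 mitochondrially encoded genes of that list was measured, so it was not analysed here. In every library, all values were whole multiples of the value of 1 read within 0.001, 100% of values. These whole reads gave the depth of each library, 7.11 to 11.3 M reads, and were used for edgeR and DESeq2 as alternatives only. The labels do not say whether counting used strand, so overlapping genes, antisense genes and close gene copies, such as the metallothioneins and the hemoglobins, are uncertain.

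The main tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options) on log2 of the deposited value plus 1, over genes with a mean of at least 10, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. The RV and LV were each tested as nPAB against Sham, and the difference between ventricles as log2 RV minus log2 LV per mouse, paired by the number in the sample titles. Gene lists (48 in all, 46 for testing) were fixed before the data were examined and tested with camera at an inter-gene correlation of 0.01 where at least 5 members were measured, which left 42. The sex-linked and RNA-quality lists were only described. Camera with an estimated correlation and fry were alternatives. Genes named in the text were chosen by a rule fixed beforehand. It takes 12 marker genes, the 6 largest rises and falls (5 for the difference) among called genes with a mean of at least 50 and no overlap of the groups, passing over provisional gene symbols, and up to 4 members with the smallest p of each described list. Described were the called lists and always the hypertrophic, S-phase, G2/M, fibrillar collagen and fatty acid oxidation lists. Some genes that the rule names are not reported here.

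The LV and RV numbers pair libraries of the same animal by the labels. This was checked by the correlation of deviations from the group means over genes tested in both tables, genes on the X and Y chromosomes left out. Same-numbered LV and RV libraries correlated at 0.132 to 0.383 in 9 mice, at 0.172 in nPAB mouse 6 and at 0.0548 in nPAB mouse 7. No 2 libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 7.47). The labels do not state litters.

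The tests were run on simulated counts drawn from the real means, dispersions and depths of 13364 genes, with 200 genes changed. A mouse effect common to both ventricles was added, of an assumed size not taken from the data, so the recovery below depends on it too. In the simulated RV comparison limma recovered 17.9%, 52.2% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold, with 7 of 115 calls outside the changed genes. In the simulated RV minus LV comparison limma recovered 0%, 1.49% and 40.9%, edgeR 7.46%, 37.3% and 78.8%, and DESeq2 13.4%, 40.3% and 86.4%. There 2 of 30 limma calls, 10 of 92 edgeR calls and 22 of 115 DESeq2 calls lay outside the changed genes. Alternatives changed the pseudocount, filter, scaling, variance model, library weights, sex term, block, count tool and list test, and left out each mouse. Crossing or leaving out nPAB mice 6 and 7 was added after the data were seen. Versions were edgeR 4.0.16, DESeq2 1.42.0 and matplotlib 3.10.9.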

Results

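RNA from the left ventricle (LV) and the right ventricle (RV) of neonatal CD1 mice, an outbred strain, was sequenced in bulk. Neonatal pulmonary artery banding (nPAB), which narrows the outlet of the RV and raises its pressure load, was performed on postnatal day 1. Sham-operated mice served as controls, and hearts were taken 7 days after surgery. The series held 22 libraries, an LV and an RV library from each of 6 nPAB and 5 Sham mice, all with batch label 1. Whole reads recovered from the deposited values summed to between 7.11 and 11.3 M reads per library. The group means were 9.47 ± 0.550 M (SD, n = 6) in RV nPAB, 8.61 ± 1.29 M (n = 5) in RV Sham, 9.73 ± 1.22 M (n = 6) in LV nPAB and 8.10 ± 0.640 M (n = 5) in LV Sham. Xist, transcribed from the inactive X chromosome, and the Y-linked gene Ddx3y gave 1 sex for both libraries in 9 of the 11 mice. In nPAB mouse 6 the LV library was male (Xist 0.830, Ddx3y 1058) and the RV library female (Xist 3040, Ddx3y 0). In nPAB mouse 7 the LV library was female (Xist 3323, Ddx3y 0) and the RV library male (Xist 1.86, Ddx3y 1175). By these genes, neither of these labelled pairs came from 1 animal. This bears on every comparison that joins the LV and RV of a mouse. Exchanging 1 LV with 1 RV library of these mice cannot give these sexes by itself. A mix-up of more libraries, which would also enter the comparisons within a ventricle, was not excluded. Without mice 6 and 7, a setting chosen after seeing the data, 2798 genes were called in the RV and 668 in the LV, against 2999 and 1260 with them.

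The first comparison asked what banding changed in the RV, the ventricle that pumps against the band. The largest changes were rises of genes known from the stressed and fetal heart. Nppa, which encodes atrial natriuretic peptide, was at 4348 ± 2385 normalized counts (SD, n = 6) against 62.3 ± 36.7 in Sham (n = 5) (log2 fold change 6.09 ± 0.54 SE, adjusted p = 6.59e-05). Acta1, skeletal muscle alpha-actin, was at 21567 ± 8320 against 388 ± 260 (log2 fold change 5.86 ± 0.43 SE, adjusted p = 2.25e-05). Ucp3, a mitochondrial carrier linked to fatty acid use, fell from 626 ± 58.5 to 96.4 ± 36.7 normalized counts (log2 fold change -2.77 ± 0.22 SE, adjusted p = 9.09e-07). All 6 nPAB libraries lay outside the range of the 5 Sham libraries for each of these genes. Nppa (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079), Acta1 (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751) and Ucp3 (ENSMUSG00000032942, chromosome 7, 100472990 to 100486432) are protein-coding genes placed here by their gene bounds in mm10. In all, 1519 genes rose and 1480 fell among 13660 tested with limma at a Benjamini-Hochberg adjusted p under 0.05, 390 and 359 of them by at least 2-fold. Of the 13660 tested genes, 1672 were called and had no overlap between the groups' libraries, a separation that chance gives to 0.433% of all genes. The call itself favours such genes, so their share among the calls is no separate evidence.

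Of the other marker genes, Nppb (B-type natriuretic peptide) rose (log2 fold change 3.87 ± 0.42 SE, adjusted p = 2.29e-04). Ankrd1, a stretch-responsive muscle protein, rose by 1.66 (adjusted p = 0.00414) and Ccn2, a matricellular protein, by 1.25 (adjusted p = 0.00588), both log2 fold changes. The myosin heavy chain genes did not pass, with 0.36 (adjusted p = 0.544) for Myh7 and -0.16 (adjusted p = 0.210) for Myh6, and without nPAB mouse 5 Myh7 was at 0.06. Neither did the proliferation genes Mki67 at -0.03 (adjusted p = 0.958), Top2a at 0.00 (adjusted p = 0.999) and Ccnb1 at 0.35 (adjusted p = 0.367). Col1a1 at -0.13 (adjusted p = 0.457) and Postn at 0.11 (adjusted p = 0.541), genes of the fibroblast matrix, did not pass either. The largest other rises among genes with a mean of at least 50 and no overlap were those of the protease Adamts20 (5.37), the poly(A) polymerase Tent5b (5.10), Sypl2 (4.97) and the lipoprotein receptor Lrp8 (4.87). Among the largest falls were those of the desaturase Scd4 (-3.60), Lrrc15 (-3.17), the water channel Aqp4 (-2.90) and the vessel-stabilising ligand Angpt1 (-2.32).

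Across the gene lists, the hypertrophic and fetal-program list had the highest median log2 fold change of the lists tested in the RV, 1.52. In it 15 of 21 measured members rose, 1 fell and 5 did not pass, against 17 rising and 1 falling when adjusted over the list alone (camera adjusted p = 3.48e-14, and adjusted p = 0.190 with an estimated correlation). Xirp2, an actin-binding protein of the intercalated disc, rose by 3.87 and the calcineurin regulator Rcan1 by 1.58. Of the glycolysis genes 18 of 22 measured members rose, 0 fell and 4 did not pass, against 18 rising and 0 falling when adjusted over the list alone (camera adjusted p = 2.60e-15, and adjusted p = 0.210 with an estimated correlation). The lactate exporter Slc16a3 rose (log2 fold change 3.89 ± 0.25 SE, adjusted p = 7.85e-08), Ldha by 1.07 (adjusted p = 8.63e-07) and the phosphofructokinase Pfkp by 1.56 (adjusted p = 1.84e-06). Of the fatty acid oxidation genes 1 of 31 measured members rose, 16 fell and 14 did not pass, against 1 rising and 17 falling when adjusted over the list alone (camera adjusted p = 1.68e-07, and adjusted p = 0.356 with an estimated correlation). Besides Ucp3, the pyruvate dehydrogenase kinase Pdk4 fell by 1.70 on the log2 scale and the carnitine transferase Cpt1a by 0.56. Of the glucocorticoid-responsive genes 12 of 19 measured members rose, 2 fell and 5 did not pass, against 13 rising and 2 falling when adjusted over the list alone (camera adjusted p = 5.53e-06, and adjusted p = 0.330 with an estimated correlation), with Sgk1 at 1.62 (adjusted p = 1.84e-06) and Per1 at 1.96 (adjusted p = 1.63e-05). For hypoxia-responsive genes, 14 of 22 measured members rose, 0 fell and 8 did not pass, against 14 rising and 0 falling when adjusted over the list alone (camera adjusted p = 6.23e-08, and adjusted p = 0.309 with an estimated correlation). These included Bnip3 at 2.03 and Egln3 at 1.67. For immediate early genes, 12 of 21 measured members rose, 0 fell and 9 did not pass, against 14 rising and 0 falling when adjusted over the list alone (camera adjusted p = 6.23e-08, and adjusted p = 0.190 with an estimated correlation). These included Nr4a3 at 2.79 and Nr4a1 at 2.29.

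Proliferation lists did not pass in the RV. Of the S-phase genes 1 of 30 measured members rose, 0 fell and 29 did not pass, against 1 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.447), the riser being Ccne1 at 1.19 (adjusted p = 0.00483). Of the G2/M genes 1 of 34 measured members rose, 0 fell and 33 did not pass, against 0 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.726), the riser being the centromere histone Cenpa at 0.51 (adjusted p = 0.0216). Fibrillar collagen and matrix genes went both ways and the list did not pass: 10 of 33 measured members rose, 2 fell and 21 did not pass, against 11 rising and 3 falling when adjusted over the list alone (camera adjusted p = 0.0876). Its members included Bgn at 0.79 (adjusted p = 5.49e-04) and Pcolce at 0.54 (adjusted p = 0.00122), and Col3a1 fell, at -0.56 (adjusted p = 7.26e-04). For activated fibroblast and matricellular genes, 10 of 31 measured members rose, 2 fell and 19 did not pass, against 13 rising and 2 falling when adjusted over the list alone (camera adjusted p = 7.05e-04, and adjusted p = 0.363 with an estimated correlation). These included Timp1 at 1.06 and Thbs1 at 1.54. For basement membrane genes, 7 of 17 measured members rose, 1 fell and 9 did not pass, against 8 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.00595, and adjusted p = 0.434 with an estimated correlation). These included Col4a1 at 0.62. TGF-beta target genes (8 of 18 measured members rose, 0 fell and 10 did not pass, against 9 rising and 0 falling when adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.350 with an estimated correlation) and BMP target genes (6 of 14 measured members rose, 0 fell and 8 did not pass, against 6 rising and 0 falling when adjusted over the list alone; camera adjusted p = 0.0164, and adjusted p = 0.330 with an estimated correlation) included Smad7 at 1.10 and Id1 at 1.17.

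Smaller RV lists were called as well. For heat shock genes, 8 of 17 measured members rose, 1 fell and 8 did not pass, against 9 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.00655, and adjusted p = 0.330 with an estimated correlation). These included Hspb7 at 0.74. For integrated stress response genes, 8 of 29 measured members rose, 0 fell and 21 did not pass, against 9 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.00784, and adjusted p = 0.233 with an estimated correlation). These included Atf3 at 1.78. For cholesterol synthesis genes, 8 of 21 measured members rose, 0 fell and 13 did not pass, against 10 rising and 0 falling when adjusted over the list alone (camera adjusted p = 7.05e-04, and adjusted p = 0.363 with an estimated correlation). These included Sqle at 1.24. Ribosomal protein genes moved little (6 of 33 measured members rose, 0 fell and 27 did not pass, against 6 rising and 0 falling when adjusted over the list alone; median log2 fold change 0.13; camera adjusted p = 1.69e-04, and adjusted p = 0.434 with an estimated correlation). Conduction and chamber markers lay lower as a list (0 of 9 measured members rose, 4 fell and 5 did not pass, against 0 rising and 4 falling when adjusted over the list alone; camera adjusted p = 0.0114, and adjusted p = 0.330 with an estimated correlation), with Cacna1g, a T-type calcium channel, at -1.24 and the ventricular factor Irx4 at -0.47. For atrial markers, 5 of 12 measured members rose, 0 fell and 7 did not pass, against 5 rising and 0 falling when adjusted over the list alone (camera adjusted p = 9.00e-04, and adjusted p = 0.350 with an estimated correlation). These included Nppa and Clu (2.32), while Myl7, named after its values were seen, ran from 72.0 to 6143 over the 11 RV libraries and did not pass. Of 42 lists tested, 16 were called, and none was called with an estimated correlation. Other drawn groupings of the 11 mice called up to 20 lists, so the number of lists says less than the genes in them.

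**Figure D1:**
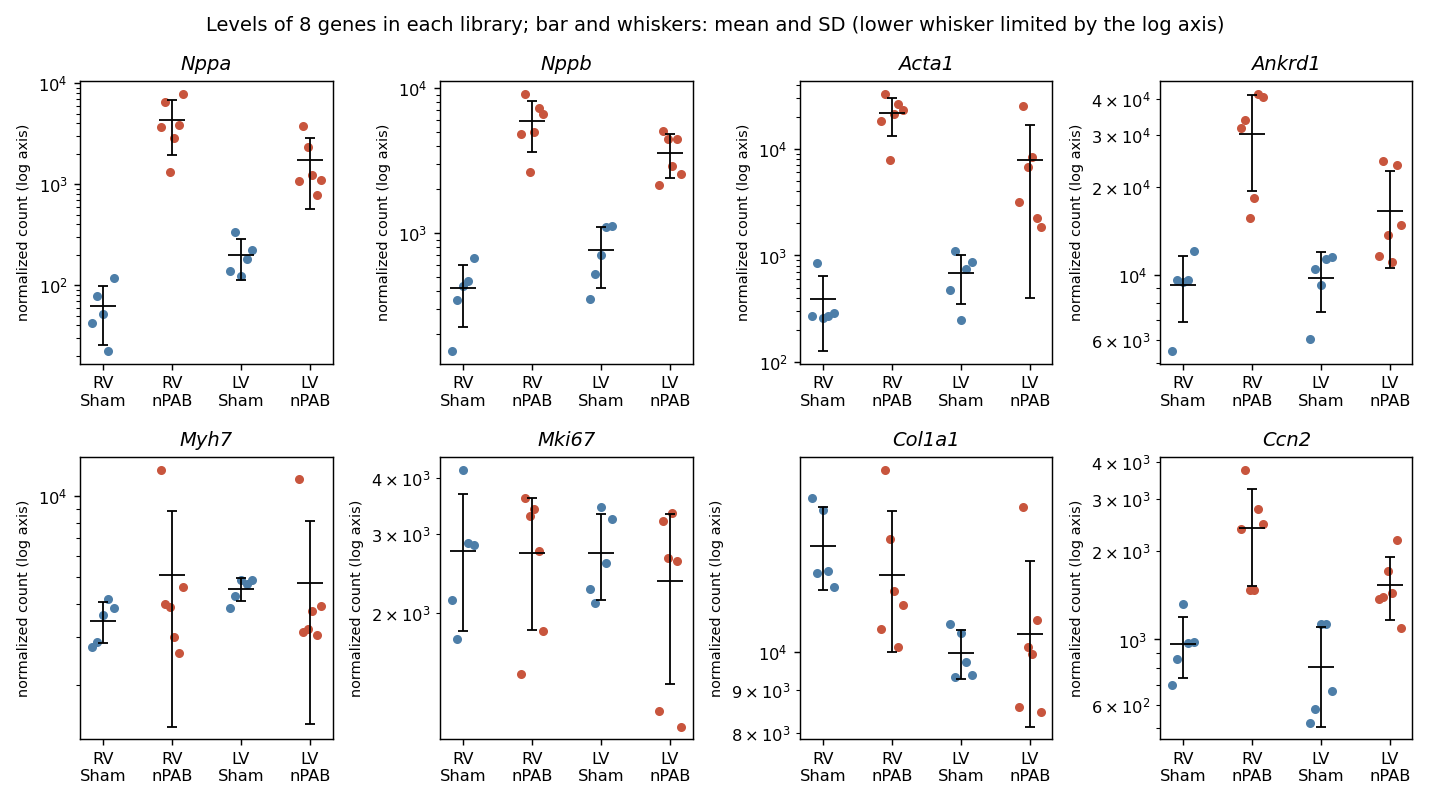
Normalized counts (log axis) of 8 genes in each library of RV and LV from Sham (blue, n = 5) and nPAB (red, n = 6) mice, with group mean and SD. Nppa, Nppb and Acta1 were higher in every nPAB library than in any Sham library of the same ventricle, while Mki67 and Col1a1 overlapped.

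The second comparison concerned the LV, the ventricle opposite the band, which the series names as its subject. The LV of nPAB mice changed too. Nppa was at 1720 ± 1154 normalized counts (SD, n = 6) against 200 ± 86.7 in Sham (n = 5) (log2 fold change 2.96 ± 0.44 SE, adjusted p = 0.00373). Per1, a clock gene that glucocorticoids also induce, was at 332 ± 43.7 against 76.2 ± 20.8 (log2 fold change 2.14 ± 0.17 SE, adjusted p = 9.79e-07). Pdk4, which restrains glucose oxidation, fell from 10948 ± 879 to 3450 ± 766 (log2 fold change -1.69 ± 0.14 SE, adjusted p = 1.21e-05). All 6 nPAB libraries lay outside the Sham range for each of these genes. In all, 644 genes rose and 616 fell among 13528 tested with limma, 147 and 105 of them by at least 2-fold. Of the 13528, 726 were called and had no overlap between groups, against a chance share of 0.433% of all genes. The number of calls was 739 without the variance trend and robust option, and 668 without nPAB mice 6 and 7, an alternative chosen after the data were seen.

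Among the marker genes, Acta1 rose (log2 fold change 3.08 ± 0.71 SE, adjusted p = 0.0281), with a mean of 7921 ± 8807 against 687 ± 332 normalized counts and 25090 in nPAB mouse 6. Nppb rose by 2.30 (adjusted p = 0.00496) and Ccn2 by 0.97 (adjusted p = 0.0298). Acta1 passed in 18 and Ccn2 in 16 of 25 alternatives. Ankrd1 did not pass, at 0.73 (adjusted p = 0.123), and neither did Myh7 at -0.12 (adjusted p = 0.872) or Myh6 at -0.06 (adjusted p = 0.747). Without nPAB mouse 5 Myh7 was at -0.41 (adjusted p = 0.00767). Mki67 at -0.31 (adjusted p = 0.622), Top2a at -0.29 (adjusted p = 0.743) and Ccnb1 at -0.08 (adjusted p = 0.928) did not pass, nor did Col1a1 at 0.05 (adjusted p = 0.832) and Postn at 0.24 (adjusted p = 0.351). The largest rises among genes with a mean of at least 50 and no overlap were those of Tent5b (4.16), the nuclear receptor Nr4a3 (3.11), Acta1, the metallothionein Mt2 (3.03), Nppa and Slc16a3 (2.83). Among the largest falls were those of Ucp3 (-2.46), the kinase-anchoring protein Akap5 (-2.43), Slitrk6 (-1.87), the growth factor Fgf9 (-1.84) and the lipase inhibitor Angptl4 (-1.84).

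In the LV, 13 of 19 measured glucocorticoid-responsive genes rose, 2 fell and 4 did not pass, against 14 rising and 2 falling when adjusted over the list alone, with a median log2 fold change of 0.96 (camera adjusted p = 3.45e-10, and adjusted p = 0.128 with an estimated correlation). Sgk1 rose by 1.39 and Klf9 by 0.71, while the members that fell were Pdk4 and Angptl4. Of the glycolysis genes 15 of 22 measured members rose, 0 fell and 7 did not pass, against 17 rising and 0 falling when adjusted over the list alone (camera adjusted p = 6.45e-16, and adjusted p = 0.0650 with an estimated correlation), with Ldha at 0.84 (adjusted p = 2.31e-06) and Gapdh at 0.68 (adjusted p = 2.51e-05). Of the hypertrophic list 11 of 20 measured members rose, 0 fell and 9 did not pass, against 13 rising and 0 falling when adjusted over the list alone (camera adjusted p = 1.47e-10, and adjusted p = 0.0650 with an estimated correlation), with the muscle LIM protein genes Fhl1 at 0.99 (adjusted p = 7.23e-05) and Csrp3 at 0.46 (adjusted p = 7.84e-04). Of the fatty acid oxidation genes 0 of 31 measured members rose, 10 fell and 21 did not pass, against 0 rising and 17 falling when adjusted over the list alone (camera adjusted p = 2.20e-08, and adjusted p = 0.323 with an estimated correlation), with the trifunctional protein subunit Hadha at -0.43 (adjusted p = 0.00665). For cholesterol synthesis genes, 8 of 21 measured members rose, 0 fell and 13 did not pass, against 13 rising and 0 falling when adjusted over the list alone (camera adjusted p = 4.71e-08, and adjusted p = 0.173 with an estimated correlation). These included Msmo1 at 1.23. For hypoxia-responsive genes, 10 of 22 measured members rose, 1 fell and 11 did not pass, against 13 rising and 1 falling when adjusted over the list alone (camera adjusted p = 7.89e-09, and adjusted p = 0.168 with an estimated correlation). These included the glucose transporter Slc2a1 at 1.23. For immediate early genes, 9 of 21 measured members rose, 0 fell and 12 did not pass, against 10 rising and 0 falling when adjusted over the list alone (camera adjusted p = 2.47e-06, and adjusted p = 0.173 with an estimated correlation). These included Nr4a1 at 2.26 and Klf4 at 0.76.

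Of the S-phase genes in the LV 0 of 30 measured members rose, 0 fell and 30 did not pass, against 0 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.344). Of the G2/M genes 0 of 34 measured members rose, 0 fell and 34 did not pass, against 0 rising and 0 falling when adjusted over the list alone, while the list as a whole lay lower, with a median log2 fold change of -0.25 (camera adjusted p = 0.0431, and adjusted p = 0.736 with an estimated correlation). This call held in 14 of 22 settings, and without nPAB mouse 11 Top2a went to 0.01. Bub1b was at -0.73 (adjusted p = 0.222) and Ndc80 at -0.51 (adjusted p = 0.208). Fibrillar collagen and matrix genes lay higher as a list (7 of 33 measured members rose, 0 fell and 26 did not pass, against 9 rising and 0 falling when adjusted over the list alone; camera adjusted p = 3.15e-05, and adjusted p = 0.414 with an estimated correlation), with the microfibril gene Fbn1 at 0.47 (adjusted p = 0.00102) and elastin, Eln, at 0.52 (adjusted p = 0.0106). For activated fibroblast genes, 6 of 31 measured members rose, 0 fell and 25 did not pass, against 9 rising and 0 falling when adjusted over the list alone (camera adjusted p = 1.46e-04, and adjusted p = 0.244 with an estimated correlation). These included Aspn at 0.47. For basement membrane genes, 4 of 17 measured members rose, 0 fell and 13 did not pass, against 5 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.00153, and adjusted p = 0.414 with an estimated correlation). These included Col4a2 at 0.46. TGF-beta targets (7 of 18 measured members rose, 0 fell and 11 did not pass, against 9 rising and 1 falling when adjusted over the list alone; camera adjusted p = 1.68e-04, and adjusted p = 0.128 with an estimated correlation) and BMP targets (5 of 13 measured members rose, 0 fell and 8 did not pass, against 6 rising and 1 falling when adjusted over the list alone; camera adjusted p = 0.00425, and adjusted p = 0.233 with an estimated correlation) shared Smad7 at 1.05 (adjusted p = 1.23e-04). For stress response genes, 5 of 27 measured members rose, 1 fell and 21 did not pass, against 9 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.0223, and adjusted p = 0.173 with an estimated correlation). These included Cebpb at 1.74. For heat shock genes, 6 of 16 measured members rose, 1 fell and 9 did not pass, against 7 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.314 with an estimated correlation). These included Cryab at 0.42. For antioxidant genes, 4 of 24 measured members rose, 1 fell and 19 did not pass, against 8 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.00377, and adjusted p = 0.128 with an estimated correlation). These included Gpx3 at 0.96. ER chaperone genes lay lower as a list (0 of 21 measured members rose, 2 fell and 19 did not pass, against 0 rising and 2 falling when adjusted over the list alone; camera adjusted p = 0.0105, and adjusted p = 0.378 with an estimated correlation), with Hspa5 at -0.37.

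Lists of small change were called in the LV too. Oxidative phosphorylation genes had a median log2 fold change of 0.12 with 1 riser, Sdhb at 0.23 (camera adjusted p = 6.25e-04, and adjusted p = 0.505 with an estimated correlation). Ribosomal protein genes had 2 risers, among them Rps19 at 0.39 (camera adjusted p = 1.19e-04, and adjusted p = 0.414 with an estimated correlation). Erythroid markers (camera adjusted p = 0.0441, and adjusted p = 0.345 with an estimated correlation) and type I interferon response genes, which lay lower (camera adjusted p = 0.0431, and adjusted p = 0.432 with an estimated correlation), had no member that passed. Their calls held in 15 of 22 settings and 14 of 22 settings. For atrial markers, 4 of 11 measured members rose, 0 fell and 7 did not pass, against 5 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.0446, and adjusted p = 0.414 with an estimated correlation). These included Clu at 1.22 (adjusted p = 6.30e-04), and the call held in 13 of 22 settings. Of 42 lists, 22 were called and none with an estimated correlation.

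**Figure D2:**
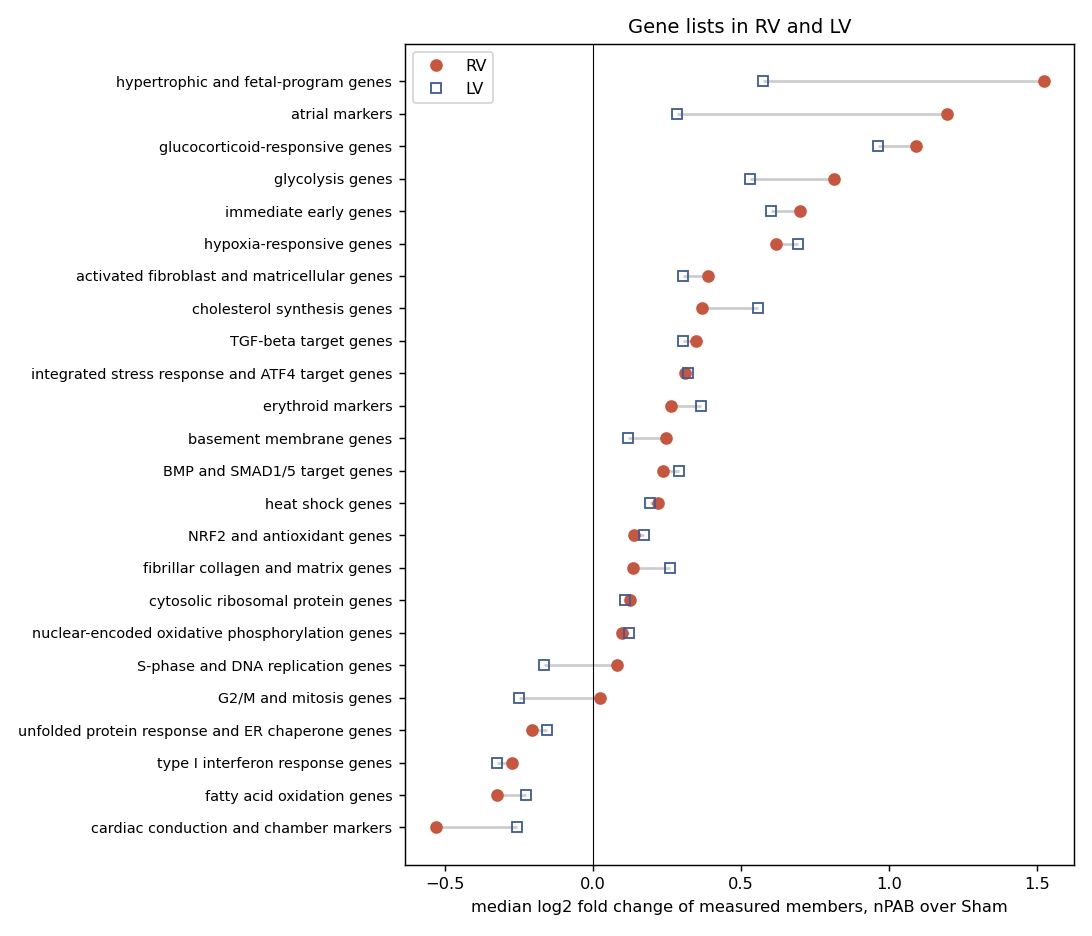
Median log2 fold change (nPAB over Sham) of the measured members of each list called in at least 1 ventricle, with the S-phase list added, in RV (filled circles) and LV (open squares). The hypertrophic list sat at 1.52 in the RV and 0.57 in the LV, and the glucocorticoid-responsive list at 1.09 and 0.96.

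The third comparison asked which changes differed between the ventricles of a mouse, from the RV minus LV difference of log2 values. Aqp4, a water channel, fell in the RV (-2.90) and was at -0.21 in the LV (adjusted p = 0.566). Its change in the RV minus that in the LV was -2.68 ± 0.32 (SE, limma adjusted p = 0.0497), lower in 6 of 6 nPAB pairs as labelled than in any Sham mouse. The hypertrophic list lay higher in the RV relative to the LV, by a median of 0.83 (camera adjusted p = 8.06e-11, and adjusted p = 0.291 with an estimated correlation), and of its 20 members 13 were higher and 1 lower when adjusted over the list alone. Of single members, Xirp2 was at 2.36 (adjusted p = 0.0535), Nppa at 3.13 (adjusted p = 0.101), Acta1 at 2.78 (adjusted p = 0.187) and Nppb at 1.58 (adjusted p = 0.123), none of which passed over all genes. Without mice 6 and 7 Xirp2 (adjusted p = 0.00925), Nppb (adjusted p = 0.00925) and Nppa (adjusted p = 0.0160) passed, and all 4 passed with edgeR on recovered reads. Of 13364 genes tested, Aqp4 was the 1 called, while 1474 had an unadjusted p under 0.05. The same question on recovered reads gave 158 genes with edgeR and 251 with DESeq2, and limma gave 35 genes with a mean value of at least 50. The count was 0 with a pseudocount of 0.5, with a sex term, with mice 6 and 7 crossed, without any 1 of the 5 Sham mice and without nPAB mouse 5, 8 or 10, and Aqp4 passed in 13 of 25 alternatives.

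Of the other lists in this comparison, G2/M genes lay higher in the RV relative to the LV by a median of 0.28 (camera adjusted p = 8.42e-06, and adjusted p = 0.647 with an estimated correlation) and S-phase genes by 0.23 (camera adjusted p = 0.00708, and adjusted p = 0.647 with an estimated correlation). No member passed over all genes; Ndc80 was at 0.80 (adjusted p = 0.307) and Gins2 at 0.55 (adjusted p = 0.274). Glycolysis genes lay higher in the RV relative to the LV (0.28; camera adjusted p = 5.93e-05, and adjusted p = 0.647 with an estimated correlation), with Pfkp at 0.73 (adjusted p = 0.287). Atrial markers also lay higher (0.60; camera adjusted p = 0.00174, and adjusted p = 0.397 with an estimated correlation), with Clu at 1.10 (adjusted p = 0.195). Resident fibroblast markers lay lower in the RV relative to the LV (-0.20; camera adjusted p = 0.0166, and adjusted p = 0.647 with an estimated correlation), with Dpt at -0.49 and Pdgfra at -0.58, neither of which passed. Complement genes lay lower likewise (-0.25; camera adjusted p = 0.0124, and adjusted p = 0.291 with an estimated correlation), with Masp1 at -0.62 (adjusted p = 0.424). Fibrillar collagen genes (median -0.09, camera adjusted p = 0.149), with Col3a1 at -0.42 (adjusted p = 0.287), and fatty acid oxidation genes (median -0.04, camera adjusted p = 0.363) did not differ past the threshold. These outcomes for single genes are those of limma. With edgeR on recovered reads Col3a1, Clu, Dpt, Pfkp and Pdgfra passed (adjusted p between 0.00586 and 0.0379), while Ndc80, Gins2 and Masp1 did not. The sex genes contradict the labelled pairing of LV and RV for mice 6 and 7, which the main test used. With these 2 mice crossed no gene passed and 7 lists did, and without them 29 genes did.

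The fourth comparison set the RV changes against the LV changes, gene by gene. Of the genes tested in both tables, 519 rose in both ventricles and 442 fell in both, and 0 were called in opposite directions. Independent lists of these sizes would share 72.3 rises and 67.0 falls. Of 1259 LV calls, 1240 had the same sign in the RV. Across 13364 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.710 and their covariance 0.177. LV and RV came from the same mice and so share chance values. In 99 other drawn groupings of the mice r had a median of 0.293 and a highest value of 0.614, and the covariance had a median of 0.0242. With the RV and LV changes taken from different mice, the median r over 100 halvings was 0.507, between 0.320 and 0.573. The median covariance of these was 0.164. With both changes taken from the same mice of a halving, the median r was 0.584. A halving uses fewer mice than the r of 0.710 did, so 0.507 is better set against 0.584. Ucp3, Pdk4 and Per1 are examples of genes with close values, with -2.77, -1.70 and 1.96 in the RV and -2.46, -1.69 and 2.14 in the LV. Equal change was not tested.

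**Figure D3:**
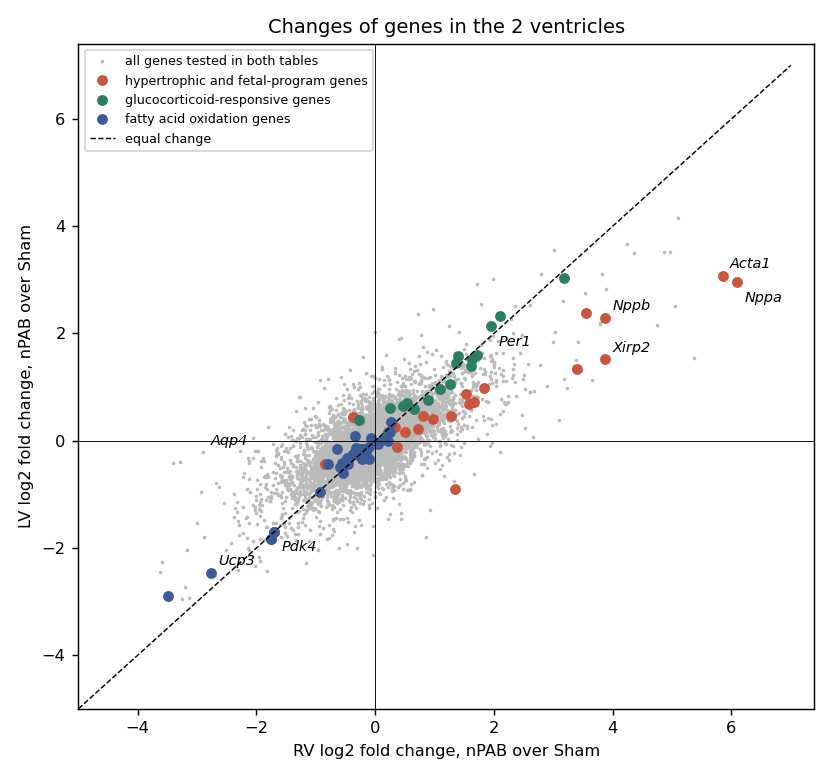
Log2 fold change (nPAB over Sham) of each gene tested in both tables, RV on the horizontal and LV on the vertical axis, with 3 lists in colour and a dashed line of equal change. Hypertrophic genes such as Nppa (6.09 in RV, 2.96 in LV) lay below the line, and Per1 (1.96, 2.14) lay near it.

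The last comparison asked whether nPAB mice with a stronger RV response had a different LV. Across the 6 nPAB mice, the RV mean of the hypertrophic genes was set against the LV mean of 3 lists, with two-sided tests over all 720 pairings. For G2/M genes, Pearson's r was -0.387 (exact permutation p = 0.435, adjusted 0.652) and Spearman's rho -0.314 (exact permutation p = 0.564, adjusted 0.803); r was 0.164 without the 2 mice farthest from the median RV value. For S-phase genes, Pearson's r was -0.438 (exact permutation p = 0.411, adjusted 0.652) and Spearman's rho -0.143 (exact permutation p = 0.803, adjusted 0.803); r was -0.404 without the 2 mice farthest from the median RV value. For fibrillar collagen genes, Pearson's r was -0.101 (exact permutation p = 0.831, adjusted 0.831) and Spearman's rho -0.143 (exact permutation p = 0.803, adjusted 0.803); r was 0.454 without the 2 mice farthest from the median RV value. None of the 3 relations passed. With mice 6 and 7 crossed, r was -0.536, -0.609 and -0.628 for the G2/M, S-phase and collagen genes. Spearman's rho was then -0.771, -0.829 and -0.600 (exact permutation p = 0.103, 0.0583 and 0.242). These were larger than as labelled but did not pass either.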

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

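The tests of tissue sharing, harvest time, exchanged mice and atrial tissue, and the drawn splits of the correlation and of single lists, were chosen after the results were seen; the drawn splits of the gene and list counts were planned. Glucocorticoid-responsive genes and hypertrophic genes differed in how far the LV followed the RV. On the scale of the deposited values, the LV change of called hypertrophic genes was a median 0.362 of the RV change (95% bootstrap interval 0.235 to 0.554), and that of called glucocorticoid-responsive genes 0.988 (0.759 to 1.18), a gap of 0.626. The share was 0.896 (0.515 to 1.10) for called fatty acid oxidation genes and 0.533 (0.393 to 0.745) for called glycolysis genes. Both intervals overlapped that of the hypertrophic genes, and the fatty acid oxidation interval also overlapped that of the glucocorticoid-responsive genes. A share near 1 was thus not particular to the latter. RV tissue in the LV libraries would give 1 share for all genes, which argues against it for the glucocorticoid-responsive genes. For the hypertrophic genes RV tissue in the LV libraries stays open. An LV library cannot hold a gene below the RV tissue share times its RV level. In nPAB mice 5, 8, 10 and 11, 4 of 60 values of these genes lay below the lower bound of the share needed in that mouse. None of them was in mice 5 and 8. That bound was drawn from the same genes, so few values could lie below it and the count does not decide the question. The labels do not say which sample holds the septum, so part of a shared change may be shared tissue. Another time of day at harvest cannot be told apart from a hormonal response to the band, which was not tested: 4 of 8 other clock genes passed in the RV (Nr1d1 at 0.67, Hlf at -0.57) and 0 in the LV.

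LV and RV libraries of nPAB mice 6 and 7 were of different sex. Over 127 genes with mouse-specific levels chosen in the other 9 mice, none on the X or Y chromosome, the crossed pairing correlated better than the labelled one, by 0.226 (95% bootstrap interval 0.0269 to 0.478), while in the 16 other pairs of mice crossing lowered r, with a difference of at most -0.298. Reads of the other mouse mixed into a library are argued against, because the gene of the other sex reached at most 0.0552% of its level in libraries of that sex. LV 7 fitted RV 6 (r = 0.851) better than RV 7 (0.610), and LV 6 fitted RV 7 (0.526) better than RV 6 (0.314). RV 6 likewise fitted LV 7 better than LV 6, while RV 7 fitted LV 7 better than LV 6. Over all genes the labelled pairs had a mean r of 0.113 against 0.0685 crossed. An exchange of the 2 mice within a ventricle therefore stays open. Undoing an exchange of 1 LV with 1 RV library would still leave each mouse with both sexes, which argues against it alone. A mix-up of more libraries across the ventricles stays open. Between RV and LV of the Sham mice limma called 0 genes (710 with an unadjusted p under 0.05), so the libraries were scored on 25 genes at least 2-fold higher and 4 at least 2-fold lower in the RV, without overlap of the libraries. These genes did not part the ventricles in nPAB mice 5, 8, 10 and 11 (on a scale with their LV mean at 0 and RV mean at 1, LV up to 0.726 and RV down to 0.0356). On this scale the Sham RV libraries lay at -4.37 to -2.75 and the Sham LV libraries at -0.450 to 0.0228. The order of the ventricle means in these nPAB mice was thus the reverse of that in Sham mice. A high score is therefore no mark of RV tissue. The place of LV 6, at 1.15 or -0.653 from the midpoint towards its own ventricle, therefore decides nothing. Acta1 in LV 6 (25090 normalized counts) lay above every other nPAB LV library, and in RV 7 (7897) below every other nPAB RV library. No biological explanation was tested.

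Atrial markers were higher in the RV of nPAB mice, and atrial tissue in the RV libraries could raise them. With the mean level of Myl7, Myl4 and Sln as a covariate, 5 of 5 other called atrial markers still passed, Nppa at 5.59 ± 0.56 (SE) against 6.09 ± 0.54 without it, which argues against atrial tissue as the whole cause. Dkk3 went from 1.06 to 0.60, and RV calls over all genes from 2999 to 1801. Of the atrial markers not called without the covariate, Stard10 (-1.67, limma adjusted p = 0.00367) and Tbx5 (-0.88, limma adjusted p = 0.0489) passed with it as lower. Nr2f2 and Bmp10 did not pass. A response of the RV muscle to the band, which the design names, remains as a hypothesis, and the spread of Myl7, Myl4 and Sln themselves stays open.

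Changes that differed between the ventricles by the test of the difference were those of Aqp4 (-2.68, RV minus LV) and, as medians, of the hypertrophic (0.83), S-phase (0.23), G2/M (0.28), resident fibroblast (-0.20), glycolysis (0.28), atrial (0.60) and complement (-0.25) lists. None of the 7 lists was called with an estimated correlation and 1 was with fry. Over the settings with the preset correlation, S-phase was called in 20 of 24 settings, resident fibroblast in 21 of 24 settings and complement in 21 of 24 settings, and Aqp4 passed in 13 of 25 alternatives. In the female LV library of nPAB mouse 8, Ddx3y stood at 8.45 normalized counts, against 0 in the female Sham LV libraries.

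Single libraries lay far from the others of their group in 20 of 384 groups of values, where chance at 1 in 20 gives 19.2; the value in brackets is the gap to the next library as a share of the group's range on the log2 scale. In RV Sham these were Acta1 in mouse 10 (high, 0.917), Scd4 in mouse 9 (low, 0.771), Angpt1 in mouse 10 (low, 0.811), Rcan1 in mouse 13 (high, 0.809), Pcolce in mouse 10 (high, 0.825), Cacna1g in mouse 9 (low, 0.924), Nr4a1 in mouse 13 (low, 0.824). In RV nPAB they were Myh7 in mouse 5 (high, 0.639), Ccne1 in mouse 11 (low, 0.671). In LV Sham they were Pkm in mouse 10 (low, 0.720), Rps19 in mouse 11 (high, 0.838), Hbb-bt in mouse 12 (low, 0.790). In LV nPAB they were Myh7 in mouse 5 (high, 0.811), Tent5b in mouse 10 (low, 0.858), Akap5 in mouse 10 (high, 0.680), Sdhb in mouse 11 (high, 0.750), Skil in mouse 11 (low, 0.633), Id1 in mouse 10 (high, 0.696), Pdia6 in mouse 11 (low, 0.702), Cyp51 in mouse 11 (low, 0.706).

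Drawn groupings of the 11 mice, 100 including the real one, gave at most 2 genes in the RV against 2999 and at most 13 in the LV against 1260. Only the real grouping was as large in each case, which argues against chance for both counts. The correlation of 0.710 was reached by 1 grouping, the real one (highest other 0.614). For the RV minus LV difference 5 groupings gave as many genes as the 1 found (highest other 1), so chance is not excluded. List counts with a preset correlation were reached by 21 groupings in the RV (16 lists, highest other 20) and 29 in the difference (7, highest other 15), where chance is not excluded. In the LV only the real grouping reached 22 lists, but another reached 20. Several single LV lists were matched by many groupings, so chance is not excluded for that count either. The number of groupings with a camera p as small, the real one included, was for the RV lists hypertrophic 1, glycolysis 1, integrated stress response 1, immediate early 3, heat shock 3, fatty acid oxidation 6, hypoxia-responsive 7, TGF-beta target 9, atrial 11, conduction 11, glucocorticoid-responsive 11, BMP target 13, ribosomal protein 17, cholesterol synthesis 20, activated fibroblast 21, basement membrane 24. For the LV lists it was hypertrophic 1, glycolysis 1, TGF-beta target 2, glucocorticoid-responsive 2, hypoxia-responsive 3, integrated stress response 3, antioxidant 4, fatty acid oxidation 5, cholesterol synthesis 5, BMP target 6, immediate early 6, activated fibroblast 9, heat shock 11, ribosomal protein 13, erythroid 20, basement membrane 22, ER chaperone 22, fibrillar collagen 24, atrial 24, type I interferon response 36, oxidative phosphorylation 43, G2/M 71. For the lists of the difference it was hypertrophic 1, complement 1, atrial 2, glycolysis 5, G2/M 6, S-phase 8, resident fibroblast 9.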

How the results depend on the processing

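Alternatives that crossed or left out nPAB mice 6 and 7 were chosen after seeing the data. Calls in the RV stayed within 1.5 times of 2999 in the alternatives for processing (2399 to 3015 without 1 mouse, 2973 with edgeR, 3354 with DESeq2). LV calls fell from 1260 to 739 without trend and robust options and to 668 without mice 6 and 7 (fewer samples), and ran from 841 to 1290 without 1 mouse, 1204 with edgeR and 1680 with DESeq2. The 1 call of the RV minus LV difference became 0 with a pseudocount of 0.5, 0 with a sex term, 0 with mice 6 and 7 crossed, 2 with quantile normalization, 9 with library weights, 35 with a mean of at least 50, 29 without mice 6 and 7, 158 with edgeR and 251 with DESeq2, and ran from 0 to 20 without 1 mouse (11 without nPAB mouse 6, 20 without nPAB mouse 7); without the pairing by mouse (no replicate block) it was 5. Lists fell to 0 in the RV, 0 in the LV and 0 in the difference with an estimated correlation, numbered 1 in the difference with fry and 25 in the RV without a filter, and ran from 5 to 11 in the difference without 1 mouse (the highest without nPAB mouse 7). The correlation of RV and LV changes was 0.464 without a filter, 0.726 with a pseudocount of 5, 0.782 with a mean of at least 50, 0.624 without mice 6 and 7 and 0.658 to 0.715 without 1 mouse. Genes that changed sign, none past the threshold as reported or after the sign change, were Ccnb1 in LV (-0.08 as reported) 0.00694 (weights), 0.178 (block, column name), 0.0725 (edgeR), 0.0645 (DESeq2), -0.246 to 0.178 without 1 mouse, then Col1a1 in LV (0.05 as reported) -0.0508 (quantiles), -0.0752 (no mice 6 and 7), -0.0547 to 0.107 without 1 mouse, then Mki67 in RV (-0.03 as reported) 0.0710 (block, column name), -0.177 to 0.137 without 1 mouse, then Myh6 in LV (-0.06 as reported) 0.0527 (no mice 6 and 7). Further such genes were Myh7 in LV (-0.12 as reported) 0.0805 (no mice 6 and 7), 0.0745 (edgeR), 0.0752 (DESeq2), then Postn in RV (0.11 as reported) -0.111 (quantiles), then Top2a in LV (-0.29 as reported) 0.0125 (block, column name), -0.437 to 0.0125 without 1 mouse, then Top2a in RV (0.00 as reported) -0.0287 (upper quartile), -0.0712 (quantiles), -0.0496 (weights), -0.0236 (sex term), -0.223 (no mice 6 and 7), -0.0171 (block, title), -0.174 to 0.204 without 1 mouse. With the 2 mice farthest from the median RV value left out the relation r turned to 0.164 for G2/M and 0.454 for collagen genes, and with RV Nppb alone to 0.193 for collagen genes. Apart from having fewer genes or samples, the cause was not tested. The block by column name left out nPAB mouse 11, so its sign changes repeat those of the fit without that mouse. Upper-quartile rescaling gave 1348 RV rises and 1677 falls. Nothing in the labels ties nPAB and Sham mice of 1 number, whose deviations correlated at -0.0624 to 0.112; with that number as a replicate block 2569 RV and 1201 LV genes were called. Of 5941 values of named genes under alternatives, 5610 kept direction and side of the threshold, 228 lost the call, 69 gained it and 34 changed sign.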

Other observations

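The genes in this part were chosen after their values were seen. The fixed list of cell-cycle inhibitors and cycle-exit regulators went both ways and did not pass camera (adjusted p = 0.622 in the RV and 0.202 in the LV), and single genes do not stand for it. Meis1, a factor known to promote cycle exit of cardiomyocytes, fell (log2 fold change -0.94 in the RV and -0.69 in the LV; adjusted p = 5.42e-05 and 0.00396). Cdkn1a, a cyclin-dependent kinase inhibitor, rose (1.09 in the RV and 0.96 in the LV; adjusted p = 1.17e-04 and 0.00618). The growth factors Fgf9 (-1.72 in the RV and -1.84 in the LV) and Igf2 (-0.49 in the RV and -0.38 in the LV) fell, and the secreted factor Fstl1 rose (0.66 in the RV and 0.57 in the LV), all with adjusted p under the threshold in both. The neuregulin receptor gene Erbb2 fell in both (-0.65 in the RV and -0.72 in the LV), and Erbb4 fell in the RV at -0.96 (adjusted p = 1.96e-05) and was at -0.31 (adjusted p = 0.140) in the LV. Of the list of growth factors and receptors, 6 of 38 measured members rose, 6 fell and 26 did not pass, against 6 rising and 6 falling when adjusted over the list alone in the RV. In the LV 2 of 38 measured members rose, 4 fell and 32 did not pass, against 2 rising and 4 falling when adjusted over the list alone. The list did not pass camera (adjusted p = 0.726 and 0.326). The apelin receptor Aplnr fell in both (-1.07 in the RV and -1.25 in the LV), as did the developmental factors Sox4 (-1.52 in the RV and -1.36 in the LV) and Prox1 (-1.34 in the RV and -1.18 in the LV).

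The calcium pump Atp2a2 was at -0.76 (adjusted p = 1.89e-04) in the RV and -0.24 (adjusted p = 0.137) in the LV. Its regulator Pln was at -0.64 (adjusted p = 1.85e-04) and -0.32 (adjusted p = 0.0818). The RV minus LV differences were -0.51 (adjusted p = 0.328) and -0.32 (adjusted p = 0.451), which did not pass with limma. With edgeR on recovered reads that of Atp2a2 passed (-0.52, adjusted p = 0.0186) and that of Pln did not. The thyroid hormone receptor gene Thrb fell in the RV at -1.30 (adjusted p = 2.57e-04) and was at 0.04 (adjusted p = 0.933) in the LV. Its difference was -1.35 (limma adjusted p = 0.0705). It passed with edgeR on recovered reads (adjusted p = 0.00656) and with limma at a mean value of at least 50 (adjusted p = 0.0308). The deiodinase gene Dio2 rose in the RV at 1.54 (adjusted p = 6.73e-05). Txnip, which restrains glucose uptake, fell in both (-1.83 in the RV and -1.60 in the LV). Of the maturation genes 5 of 26 measured members rose, 9 fell and 12 did not pass, against 7 rising and 9 falling when adjusted over the list alone in the RV and 2 of 26 measured members rose, 4 fell and 20 did not pass, against 4 rising and 6 falling when adjusted over the list alone in the LV. Macrophage markers had 2 falls and no rise in the RV and no call in the LV. In Sham mouse 13, the class I gene H2-K1 stood at 6295 normalized counts in the RV and 4746 in the LV and Cd74 at 630 and 410; among the other 10 mice H2-K1 reached at most 1309 and Cd74 at most 62.7.

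Other lists had the following numbers of rising and falling members. Endothelial genes had 5 and 2 in the RV, 3 and 2 in the LV. Endocardial genes had 0 and 2 in the RV, 0 and 1 in the LV. Lymphatic genes had 1 and 1 in the RV, 0 and 1 in the LV. Pericyte and smooth muscle genes had 4 and 2 in the RV, 4 and 1 in the LV. Epicardial genes had 2 and 1 in the RV, 1 and 0 in the LV. Neutrophil genes had 1 and 0 in the RV, 0 and 0 in the LV. Neural crest genes had 2 and 2 in the RV, 1 and 0 in the LV. YAP/TEAD target genes had 4 and 4 in the RV, 2 and 0 in the LV. Cytokine genes had 2 and 0 in the RV, 0 and 0 in the LV. Angiogenesis genes had 5 and 6 in the RV, 2 and 5 in the LV. The p53 target genes had 4 and 0 in the RV, 2 and 1 in the LV. Apoptosis genes had 3 and 3 in the RV, 1 and 2 in the LV. Cell-cycle inhibitor genes had 6 and 5 in the RV, 3 and 5 in the LV. RNA-quality markers had 1 and 2 in the RV, 0 and 2 in the LV. Those that fell were Malat1, a nuclear RNA (-0.87 in the RV and -0.50 in the LV), and Rn7sk (-0.33 in the RV and -0.36 in the LV), and whether RNA quality contributed to the changes of other genes was not tested. Adipocyte, lymphocyte and the joint thymus, lung and skeletal muscle lists had under 5 measured members and were not tested. The adipocyte list had 2 and 0 in the RV, 1 and 0 in the LV, the lymphocyte list 0 and 0 in the RV, 0 and 0 in the LV and the joint list, which holds Acta1, 2 and 0 in the RV, 1 and 0 in the LV. Tissue of these kinds in the RV libraries was not tested.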
